A study of Mus musculus with 12 samples.

How the data were processed

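Poly(A) RNA from the livers of C57BL/6 mice, 7 weeks old by the labels, was sequenced from the 3' end in bulk. Per the labels' protocol, a barcode and a unique molecular identifier were added at reverse transcription, the samples were pooled before amplification, and the pool was sequenced on a NextSeq 500. The labels give 12 samples in 4 groups: Kupffer cells at day 0 (2 samples), Kupffer cells at day 7 (2), a group called CD40 at day 2 (4) and a group called Ly6C CD40-negative at day 2 (4). They do not say from which event the days are counted, what treatment was given, how the cells were sorted or whether each library came from a separate animal. The p-values given here therefore measure the spread between these libraries, which may in part be technical. The series title speaks of the liver as a tissue, whereas the samples carry cell type labels, and its design text gives 3 to 4 replicates, whereas the Kupffer groups have 2.

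The deposited table holds raw counts, whole numbers per gene symbol, for 25919 rows and 12 columns. Per the submitters' processing notes, the genome build was GRCm38.p6 and DESeq2 1.22.2 was used. The aligner, the counting program, the annotation release and whether the authors counted reads or molecular identifiers are not given in the sources used here. The column names give the group but no replicate number, so the columns of a group are called a, b, c and d here in the order of the table, as names only. No column belonged to no sample. Of the symbols, 17 had been turned into calendar dates and held between 0.085% and 0.195% of a column's counts.

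The order of the rows was examined before any comparison. Column a of Kupffer day 0 runs from the highest to the lowest count, and so do column a of Kupffer day 7 and column a of Ly6C CD40-negative day 2, each with 1 step up, which follows row 25917. Independent libraries with the composition of Kupffer day 0 a were simulated 100 times by Poisson sampling at the depths of these 2 columns. Whether the other columns follow the gene names was checked through groups of genes that vary together. Within a group of columns, each column's log2 ratio to column a (CPM plus 5, genes with at least 20 counts in column a, minus a running median over 200 genes of like abundance) was averaged over gene sets, and the summed squares of these means were compared with 10000 random draws matched on abundance. The gene sets were the lists fixed beforehand or, in a first form, 6 families (ribosomal proteins, mitochondrially encoded genes, haemoglobins, C1q, the S100a8 and S100a9 pair, immediate early genes). This check was designed after the data had been seen and was run in several forms, and the outcomes of all of them are reported.

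On this basis only CD40 day 2 against Kupffer day 0 was analysed by gene, on 6 libraries. The other 3 comparisons planned before the data were examined are not analysed here: Kupffer day 7 against day 0, CD40 against Ly6C CD40-negative at day 2, and Ly6C CD40-negative against Kupffer day 0. The plan had been to fit all 12 libraries together. Since the check did not show that the other 6 columns follow the gene names, the 6 libraries of the 2 groups compared were fitted alone, which had been listed as an alternative, and the fit of all 12 became the alternative.

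Within these 2 groups no pair of libraries differed as little as sampling noise (chi-square per degree of freedom 3.17 to 11.7), so none was treated as a repeat deposit of another. This does not show that they come from separate animals. Counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr with its default settings, R 4.3.3), with no block, two-sided, and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p of 0.05. Levels are CPM (counts scaled to the TMM-adjusted library total), as mean ± SD over the libraries. The standard error of a log2 fold change is the fold change over the square root of its F statistic. Gene lists, 32 in all, were fixed before the data were examined. Those with at least 5 measured genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with adjustment over the 26 lists tested. Camera with an estimated correlation and fry were the alternatives. For lists, the number of members past the threshold is also given where it changes when adjusted over the list alone. Cholangiocyte genes had no measured member, and the lists of MHC class II, plasmacytoid dendritic cells, B cells, platelets and basophils had too few for a list test.

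Genes were named by a rule fixed beforehand. A gene qualified with an adjusted p under 0.05, no overlap between the groups' libraries, a mean of at least 20 CPM, and a symbol that is no clone, predicted gene, pseudogene or locus code. The 5 largest rises and 5 largest falls among the 3202 qualifying genes were named, with Cd40, Ly6c2, Clec4f, Timd4 and Adgre1 whatever their values, and up to 4 members with the lowest adjusted p of each list that was called, 77 genes in all. Genes outside the rule are marked as such. Positions are GRCm38, from GENCODE M21 for 75 of these genes and from RefSeq for 2 whose symbols are synonyms there. Of the 75, 32 overlap another annotated gene. The sources do not say whether counting used strand, so reads of such pairs may be shared. A ratio is given with its exact 95% counting interval where a group holds 1 to 3 counts in all, and as a bound at 3 counts over the group where it holds 0. These cover counting error only.

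The scripts were tested on simulated data with the libraries, means and dispersion of this comparison. Of 9314 genes tested there, the test called 48 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and 6 of 9094 unchanged genes. A simulated list of 20 genes shifted 2-fold gave a camera p of 3.5e-26, or 0.00035 with an estimated correlation, and 1 of 100 unshifted lists had a p under 0.05. The simulated genes varied independently of each other around a common dispersion. The simulation therefore does not show how the list tests behave where genes of a list are correlated. Alternatives tried were RLE size factors, library size alone, no filter, a minimum of 10 counts in 4 libraries, DESeq2 1.42.0, the fit of all 12 libraries, a minimum log2 fold change of 1, and leaving out each library. Library size alone and the fit of all 12 libraries were chosen after seeing the data, as were RLE factors and the filters for the list tests.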

Results

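The table covers 12 libraries of mouse liver cells in 4 groups. Kupffer cells, the resident macrophages of the liver, were labelled day 0 or day 7, with 2 libraries each. The day 2 samples were labelled CD40, after a receptor of antigen-presenting cells, or Ly6C CD40-negative, Ly6C being a surface marker of inflammatory monocytes, with 4 libraries each. Total counts were 1612435 and 688498 for Kupffer day 0, and 723623 and 274041 for Kupffer day 7. They were 1182437, 725683, 2271228 and 1775691 for CD40 day 2, and 1478498, 733023, 6057253 and 5172235 for Ly6C CD40-negative day 2.

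The columns of Kupffer day 7 and Ly6C CD40-negative day 2 were not read by gene. Column a of Kupffer day 7 and column a of Ly6C CD40-negative day 2 fall along the table from the highest to the lowest count, with 1 step up each, although the rows are ordered by Kupffer day 0 a. Simulated independent libraries with the composition of Kupffer day 0 a had 6707 to 6925 steps up at the depth of the first and 7210 to 7391 at the depth of the second. The rank correlation with Kupffer day 0 a over rows with at least 20 counts was 0.9998 and 0.9999, across genes, against 0.9466 for the second Kupffer day 0 library. At the step, the row named n-R5s8, the second last of the table, holds 150 and 51 counts in Kupffer day 7 and 318, 143, 2387 and 2106 in Ly6C CD40-negative day 2, and 0 in the other 6 libraries.

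**Figure D1:**
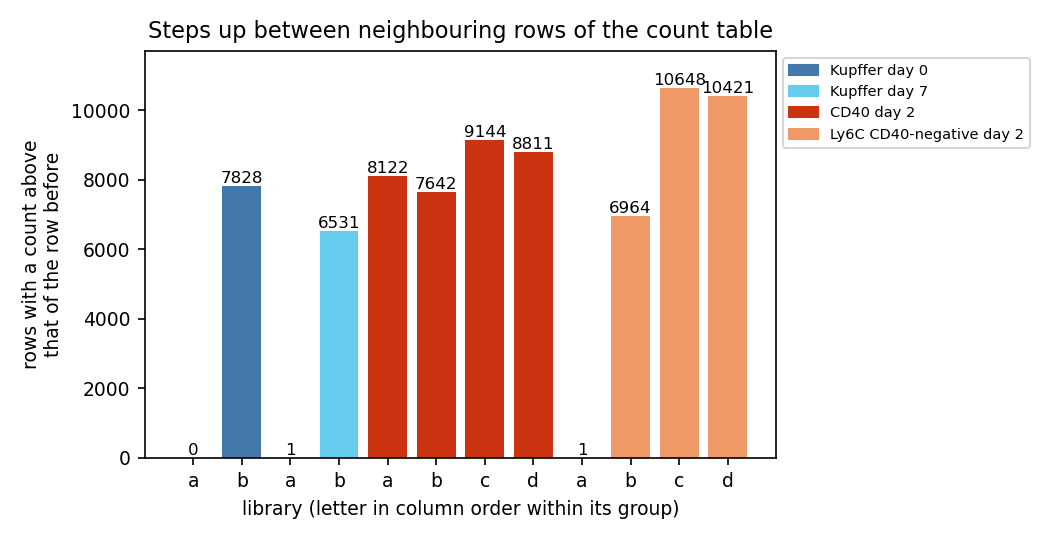
Number of rows of the count table whose count is above that of the row before, for each of the 12 libraries (bars, coloured by group). Library a has 0 steps up in Kupffer day 0 and 1 each in Kupffer day 7 and Ly6C CD40-negative day 2, where the other libraries have between 6531 and 10648.

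The check with the gene lists fixed beforehand separated the groups in the same way. In Kupffer day 0 and CD40 day 2, 4 of 4 libraries had lists that moved together against column a (p = 0.0001 each, the smallest the permutation draws can give), with a statistic 9.71 to 22.9 times the random median. In Kupffer day 7 and Ly6C CD40-negative day 2 this ratio was 0.5 to 1.69, and 1 of 4 libraries passed the threshold (permutation p = 0.047, unadjusted). When the 2 readable groups were sorted apart from their names as a control, 1 of 4 libraries passed (permutation p = 0.0065). With the 6 gene families, 4 of 4 readable libraries passed, 2 of 4 of the others (Ly6C CD40-negative c and d, permutation p = 0.018 and 0.001) and 0 of 4 controls. A statistic that divides by the spread within families, tried afterwards, gave the same numbers of calls with the 6 families. With the fixed lists it passed in 4 of 4 readable libraries, 0 of 4 of the others and 1 of 4 controls. In c and d the C1q family made the difference, but its 3 genes moved apart there (SD 1.18 and 1.85 on the log2 scale, against 0.582 and 0.654 for all genes). Without C1q, chosen after that was seen, 0 of 4 of the other libraries and 4 of 4 readable ones passed by either statistic. Without column a as the reference, 1 of 2 Ly6C CD40-negative libraries passed (d, permutation p = 0.026) and 2 of 2 CD40 libraries, and with the spread within families 2 of 2 in both groups. The check therefore does not settle whether Ly6C CD40-negative c and d keep part of the order of the names. Their rank correlation with Kupffer day 0 a over rows with at least 20 counts was 0.9102 and 0.8896. In the CD40 day 2 libraries it was 0.5866 to 0.6391. Unless these cells resembled Kupffer day 0 that closely, this argues against c and d standing wholly under their own names. Kupffer day 7 b set against Kupffer day 0 b gave a permutation p of 0.0013, or 0.0005 by the statistic that divides by the spread, which decides nothing, since Kupffer day 0 b itself departs by family. Both groups are left out of the gene analysis. Some forms passed for Ly6C CD40-negative c and d, but the forms together did not establish that the values stand under the right names.

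The remaining comparison, CD40 day 2 against Kupffer day 0, asks how libraries labelled CD40 differ from those labelled Kupffer cells. Label and day differ together, so the comparison describes both. In the Kupffer libraries the endothelial list took more of the counts (2.37% and 2.51%) than the Kupffer identity list (0.784% and 0.676%). A difference in any gene or list below may therefore rest on RNA of other cells as well as of macrophages. By camera with its preset correlation, the lists of classical monocyte, interferon and glycolysis genes stood higher in CD40 day 2, and those of Kupffer cell identity, liver endothelial cells and stellate cells lower. None of these list calls was kept with an estimated correlation (adjusted p = 0.24 to 0.3 with an estimated correlation). Cd40 itself was at 330 ± 72.6 CPM (SD, n = 4) in CD40 day 2 and 19.1 ± 1.41 CPM (n = 2) in Kupffer day 0 (log2 fold change 4.08 ± 0.3 SE, adjusted p = 4.37e-06). It lies on chromosome 2 from 165055627 to 165072948. Ly6c2, which encodes Ly6C, was at 7090 ± 1220 CPM against 585 ± 89.1 (3.6 ± 0.25, adjusted p = 2.98e-06; chromosome 15, 75108158 to 75111970). Ly6c2 has a close paralog, so its counts may hold reads of both.

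Clec4f, a lectin of Kupffer cells on chromosome 6 from 83644542 to 83656187, went the other way, with 17.2 ± 3.61 CPM in CD40 day 2 against 1070 ± 74.3 in Kupffer day 0 (-6.02 ± 0.2, adjusted p = 1.5e-07). Timd4, a receptor for dying cells on chromosome 11 from 46810800 to 46844332, was at 7.33 ± 3 against 99.2 ± 5.48 CPM (-3.89 ± 0.32, adjusted p = 8.03e-06). Adgre1, which encodes the macrophage marker F4/80, was at 99.6 ± 61.6 against 95.4 ± 8.83 CPM and did not pass the test (0.1 ± 0.48, adjusted p = 0.874). Its 4 CD40 values were 55.5, 38.2, 144 and 160 CPM.

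**Figure D2:**
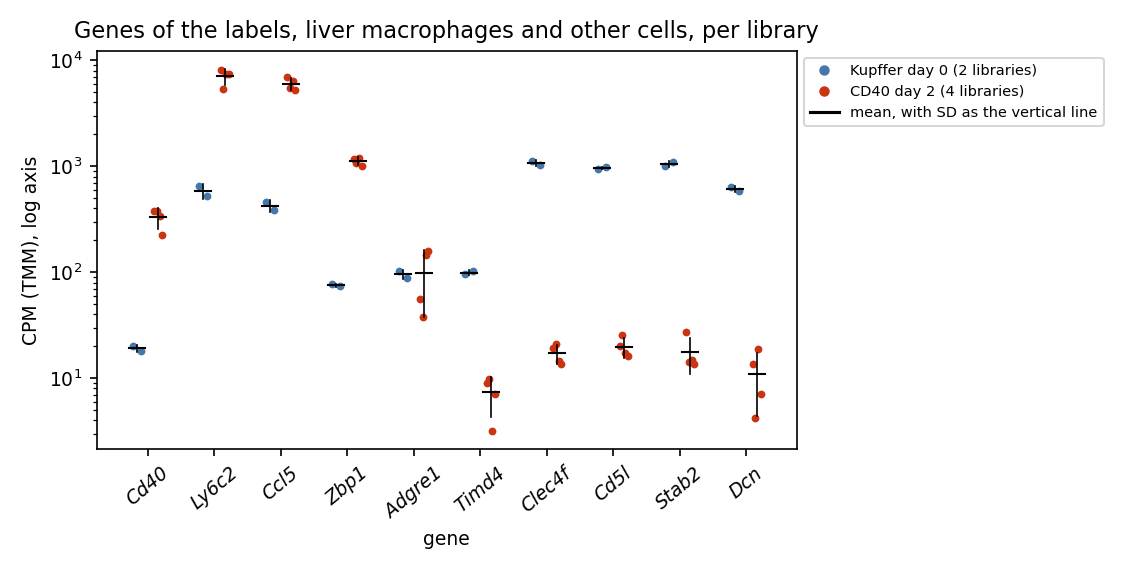
CPM (TMM-scaled, log axis) of 10 named genes in each Kupffer day 0 library (blue, n = 2) and CD40 day 2 library (red, n = 4), with horizontal lines at the means and vertical lines of 1 SD. Adgre1 overlaps between the groups, whereas Cd40 and Ly6c2 lie apart upwards and Clec4f, Stab2 and Dcn downwards.

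In all, 5262 of 9852 genes tested differed, 2288 higher and 2974 lower in CD40 day 2, and the median log2 fold change was -0.1. The groups' libraries did not overlap for 66.6% of the genes, where chance gives 13.3%. The 15 splits of 6 libraries allow no exact permutation p under 0.067, so the calls rest on the model's shared dispersion (biological coefficient of variation 20.4%). Without Kupffer day 0 a, which leaves 1 library assumed to vary like the others, 3206 genes were called.

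Among the largest rises, Bcl2l14, of the Bcl2 family, held 1 count in Kupffer day 0 and 455 in CD40 day 2, a ratio of 197 with a counting interval of 35.2 to 7800 (adjusted p = 0.00156; chromosome 6, 134396318 to 134438736). Its levels were 121, 226, 50.5 and 30.4 CPM. Defb52, of a beta-defensin cluster on chromosome 8 from 20900606 to 20902456, was at 542 ± 146 against 6.52 ± 1.34 CPM (6.3 ± 0.41, adjusted p = 2.09e-06), and may share reads with related defensin genes. Ccl12, a chemokine on chromosome 11 from 82101845 to 82103400, was at 211 ± 84.7 against 3.24 ± 1.33 CPM (6.14 ± 0.55, adjusted p = 1.42e-05). Cd200r4, an activating receptor gene on chromosome 16 from 44811733 to 44839150, rose from 1 count (ratio 87, counting interval 15.4 to 3450). Il12b, the p40 chain of interleukin-12, rose from 2 counts (ratio 77.3, counting interval 21.2 to 641; chromosome 11, 44400063 to 44414033).

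Of the largest falls, Gmpr, a GMP reductase, was at 1.17 ± 1.18 CPM against 150 ± 15.2 (-6.83 ± 0.36, adjusted p = 8.23e-07; chromosome 13, 45507444 to 45553800). Bmp6, a signal of liver endothelial cells that sets hepcidin, was at 1.2 ± 1.26 against 167 ± 61.3 CPM (-6.83 ± 0.42, adjusted p = 1.65e-06; chromosome 13, 38345107 to 38500302). Tcf7l1, a transcription factor of the Wnt pathway, was 122-fold lower (counting interval 41.1 to 600; chromosome 6, 72626378 to 72789254). Folr2, a folate receptor of resident macrophages, was at 2.94 ± 1.45 against 260 ± 14.9 CPM (-6.64 ± 0.31, adjusted p = 4.61e-07; chromosome 7, 101839988 to 101857194). Cyr61, a matrix-associated signalling protein, was at 0.867 ± 0.608 against 110 ± 5.65 CPM (-6.59 ± 0.33, adjusted p = 6.25e-07; chromosome 3, 145646971 to 145649985). Gmpr, Bmp6, Tcf7l1, Folr2 and Bcl2l14 overlap other annotated genes.

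Of 22 measured genes of Kupffer cell identity, 17 were lower and 3 higher in CD40 day 2 (18 lower when adjusted over the list alone), with a median log2 fold change of -4.91 (camera adjusted p = 2.3e-06; adjusted p = 0.24 with an estimated correlation). The 3 that rose were Il18bp, Spic and Nr1h3, chosen after their values were seen. Cd5l, a secreted scavenger receptor protein, was at 19.7 ± 4.17 against 964 ± 20.8 CPM, and Fcna, a ficolin, at 8.06 ± 2.73 against 653 ± 85.1 CPM. The Kupffer day 0 libraries also held endothelial and stellate transcripts. All 17 measured genes of liver sinusoidal endothelial cells were lower in CD40 day 2 (median -5.73, or -5.05 with genes at 0 counts set at their bound; camera adjusted p = 1.1e-09; adjusted p = 0.24 with an estimated correlation). Bmp2 fell from 1050 ± 61.5 to 13.7 ± 4.01 CPM, Ptprb, an endothelial phosphatase, from 1520 ± 118 to 28.1 ± 9.38, and Stab2, a hyaluronan receptor, from 1050 ± 62.7 to 17.5 ± 6.53. This list took 2.37% and 2.51% of counts in the Kupffer libraries, against 0.784% and 0.676% for the Kupffer identity list, and 0.0759% to 0.131% in CD40 day 2. Likewise, 10 of 10 stellate cell and fibroblast genes were lower (median -5, camera adjusted p = 1.6e-05; adjusted p = 0.24 with an estimated correlation), among them Dcn, a matrix proteoglycan, at 10.9 ± 6.49 against 607 ± 38.9 CPM, Colec11 at 3.1 ± 1.31 against 181 ± 5.66, and Reln, 75.4-fold lower (counting interval 25.1 to 372). Efferocytosis and scavenger receptor genes fell in 8 of 15 cases and rose in 2 (camera adjusted p = 0.032; adjusted p = 0.47 with an estimated correlation). Their members with the lowest adjusted p, Mrc1 (15.8 ± 5.24 against 866 ± 46.5 CPM) and Stab2, are also on the endothelial list. Gas6, a bridging ligand (7.85 ± 3.55 against 643 ± 181), had the largest fold change of the list (-6.33) and is not on the endothelial list, nor is Stab1 (28.6 ± 11.2 against 592 ± 23.6). That absence does not show that endothelial cells were not the source of their RNA, or of the fall of the efferocytosis and scavenger receptor list. Without Kupffer day 0 b this list was not called (adjusted p = 0.058, range over the alternatives 0.0072 to 0.058).

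Classical monocyte genes were higher in 17 of 20 cases and lower in 0 (18 higher when adjusted over the list alone; camera adjusted p = 1.6e-08; adjusted p = 0.3 with an estimated correlation). Besides Ly6c2, Plac8 reached 6910 ± 571 against 555 ± 20.6 CPM, Ly6i 3710 ± 854 against 137 ± 18.3, and Ms4a4c 1600 ± 237 against 71.4 ± 9.27. Non-classical monocyte genes rose in 6 of 11 cases (camera adjusted p = 0.0087; adjusted p = 0.24 with an estimated correlation), including Cx3cr1, the fractalkine receptor, at 21.2 ± 4.4 against 3.24 ± 1.33 CPM, and the transcription factors Pou2f2 (71.7 ± 7.93 against 27.5 ± 2.41) and Cebpb (804 ± 223 against 292 ± 28.4). Cx3cr1 overlaps several annotated genes. Itgax, which encodes CD11c, was at 49.3 ± 26 against 5.61 ± 3.88 CPM, a call lost without Kupffer day 0 a (adjusted p = 0.058, range over the alternatives 8.8e-14 to 0.058).

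Type I interferon response genes were higher in 26 of 39 cases and lower in 0 (28 higher when adjusted over the list alone; camera adjusted p = 1.2e-09; adjusted p = 0.24 with an estimated correlation). Zbp1, a sensor of nucleic acids, rose from 75.7 ± 2.61 to 1120 ± 91.7 CPM, Ifi27l2a from 643 ± 3.86 to 5530 ± 424, Isg15, a ubiquitin-like protein, from 183 ± 6.7 to 1070 ± 144, and Mx1, an antiviral GTPase, from 6.47 ± 2.66 to 95.5 ± 12.2. Interferon gamma and antigen processing genes rose in 21 of 25 cases and fell in 1 (camera adjusted p = 2.3e-08; adjusted p = 0.24 with an estimated correlation). Gbp2 and Gbp5, guanylate-binding proteins, were at 1800 ± 478 against 153 ± 17.5 and 126 ± 11.3 against 13.7 ± 1.69 CPM. Psme2 and Psmb10, of the immunoproteasome and its activator, were at 1020 ± 183 against 111 ± 1.77 and 1050 ± 135 against 272 ± 19.2 CPM. All 3 measured MHC class II presentation genes, Cd74, Ciita and Ctss, were higher. Many class II genes, such as H2-Ab1, are not analysed here.

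Co-stimulation and maturation genes rose in 9 of 16 cases and fell in 2 (10 higher when adjusted over the list alone; camera adjusted p = 0.0011; adjusted p = 0.38 with an estimated correlation). After Cd40, the lowest adjusted p belonged to Cd274, which encodes PD-L1 (188 ± 30.4 against 15 ± 5.52 CPM), Cd86 (179 ± 16.8 against 39.3 ± 4.44) and Il15ra (99.3 ± 13.1 against 18.7 ± 2.8). This list took 0.292% of counts in CD40 day 2 b, against 0.128% to 0.193% in the other 3, and without Kupffer day 0 a 6 members were higher and 0 lower. Genes of conventional dendritic cells rose in 6 of 12 cases and fell in 2 (9 higher when adjusted over the list alone; camera adjusted p = 0.016; adjusted p = 0.59 with an estimated correlation). Here too library b stood highest, with 0.146% of counts in CD40 day 2 b against 0.0728% to 0.0858% in the other 3. Naaa was at 551 ± 63.1 against 25.9 ± 3.15 CPM, the transcription factor Batf3 at 138 ± 33.2 against 33.5 ± 15.7, and Htr7 at least 9.38-fold higher, with 0 counts in Kupffer day 0, whereas Dpp4 was at 33.2 ± 16 against 262 ± 5.4 CPM. Without Kupffer day 0 a neither Htr7 (adjusted p = 0.052, range over the alternatives 5.1e-08 to 0.052) nor the list was called (adjusted p = 0.088), with 2 members higher and 3 lower, and the list was also lost with a minimum of 10 counts in 4 libraries (0.1, range over the alternatives 0.0028 to 0.1). Cytokine and chemokine genes moved both ways, with 15 of 23 higher and 6 lower (camera adjusted p = 0.0098; adjusted p = 0.55 with an estimated correlation). Ccl5 rose from 425 ± 54.8 to 6010 ± 814 CPM and Il1rn, the interleukin-1 receptor antagonist, from 30.5 ± 13.9 to 511 ± 96.2, while Ccl24 fell from 89.1 ± 31.5 to 4.15 ± 1.12 and Cxcl1 from 96.5 ± 40.7 to 5.08 ± 2.04. NF-kappaB targets rose in 11 of 20 cases and fell in 1 (camera adjusted p = 0.00031; adjusted p = 0.24 with an estimated correlation). Traf1 was at 397 ± 147 against 25.2 ± 0.137 CPM and Ptgs2, cyclooxygenase-2, at 76.5 ± 19.4 against 4.96 ± 1.11. Bcl2a1b and Bcl2a1d, at 266 ± 26.1 and 124 ± 19.5 CPM in CD40 day 2, are near-identical copies whose counts are uncertain one by one.

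**Figure D3:**
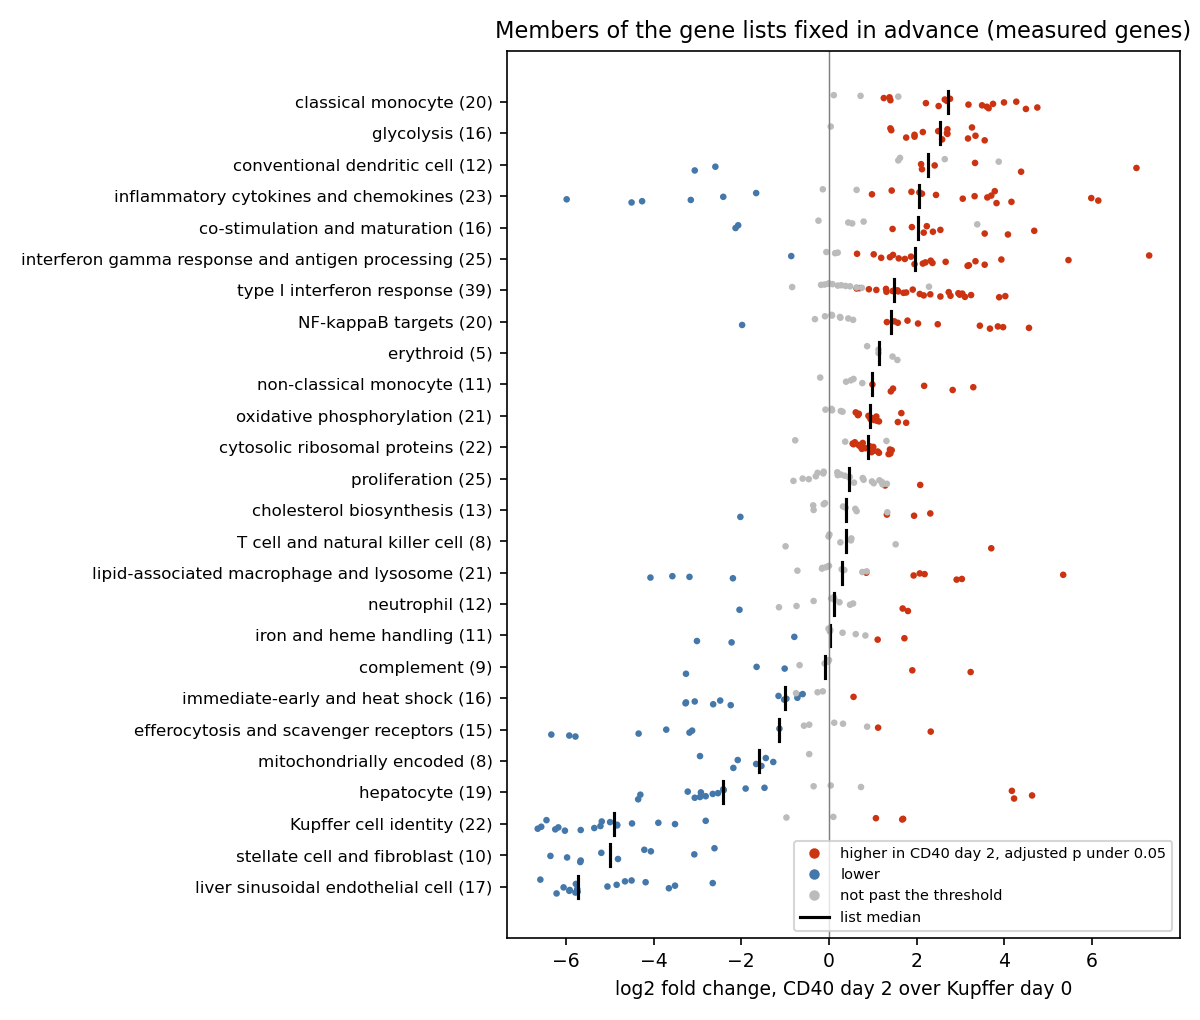
Fitted log2 fold change of every measured gene (points) in the 26 lists with at least 5 measured genes, with the number measured in brackets and black lines at the medians. The lowest medians are -5.73 for sinusoidal endothelial, -5 for stellate cell and fibroblast and -4.91 for Kupffer identity genes. The highest are 2.53 for glycolysis and 2.72 for classical monocyte genes.

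Glycolysis genes were higher in 15 of 16 cases (camera adjusted p = 1.6e-08; adjusted p = 0.24 with an estimated correlation), such as Aldoa (2330 ± 245 against 391 ± 10 CPM), Tpi1 (1220 ± 174 against 103 ± 13.6), Gpi1 (448 ± 35.3 against 132 ± 3.82) and the glucose transporter Slc2a1 (88.5 ± 16.6 against 9.75 ± 0.00823). Nuclear genes of oxidative phosphorylation were higher in 16 of 21 cases (camera adjusted p = 2.8e-06; adjusted p = 0.24 with an estimated correlation), with smaller changes, among them Cox8a at 1990 ± 72.5 against 900 ± 54.2 CPM and Sdhb at 590 ± 24.8 against 174 ± 1.31. Mitochondrially encoded genes were lower in 7 of 8 cases (camera adjusted p = 0.0011; adjusted p = 0.38 with an estimated correlation), with mt-Nd1 at 883 ± 56.9 against 2560 ± 18 CPM and mt-Cytb at 2050 ± 271 against 4960 ± 59.7. The call of mt-Cytb was lost in the fit of all 12 libraries (edgeR adjusted p = 0.056, range over the alternatives 1.2e-11 to 0.056). That fit includes columns not shown to follow the gene names, so this loss decides nothing. Cytosolic ribosomal protein genes were higher in 19 of 22 cases (camera adjusted p = 1.3e-06; adjusted p = 0.32 with an estimated correlation), with Rplp0 at 1540 ± 104 against 786 ± 36 CPM and Rps19 at 765 ± 140 against 290 ± 8.19. Immediate-early and heat shock genes, which respond to handling of cells as well as to signals, were lower in 12 of 16 cases and higher in 1 (13 lower when adjusted over the list alone; camera adjusted p = 0.0016; adjusted p = 0.47 with an estimated correlation). Klf2 fell from 3250 ± 168 to 333 ± 133 CPM, Fosb from 272 ± 115 to 28.3 ± 11.9 and Dnajb1 from 568 ± 39.7 to 120 ± 11.8. Without Kupffer day 0 b, 7 members were lower and 0 higher. This list took 2.59% and 3.14% of counts in the Kupffer libraries and 0.813% to 1.36% in the CD40 libraries.

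The other 9 lists tested were not called. Hepatocyte genes had 13 of 19 members lower and 3 higher (camera adjusted p = 0.083), at 0.142% and 0.284% of counts in the Kupffer libraries and 0.0414% to 0.101% in the CD40 libraries. Proliferation genes had 2 of 25 higher and 0 lower (camera adjusted p = 0.061; 1 higher when adjusted over the list alone). Lipid-associated macrophage and lysosome genes had 7 of 21 higher and 4 lower (camera adjusted p = 0.42), complement genes 2 of 9 higher and 3 lower (0.68), and cholesterol biosynthesis genes 3 of 13 higher and 1 lower (0.25). Iron and heme genes had 2 of 11 higher and 3 lower (0.95), with a median of 0.03, a mean of -0.13 and a downward list test. Neutrophil genes had 2 of 12 higher and 1 lower (0.52), T cell and natural killer cell genes 1 of 8 higher (0.25), and erythroid genes 0 of 5 in either direction (0.45). In lists too small for a test, 3 of 3 basophil and mast cell genes, 2 of 2 platelet genes and 2 of 3 B cell genes were lower, and plasmacytoid dendritic cell genes had 1 higher and 1 lower of 4. Clec1b, 1 of the 2 platelet genes, is also on the Kupffer cell identity list. The B cell calls rest on Kupffer day 0 b, without which 0 of 3 were called. Igkc and Jchain were chosen after their values were seen. Igkc was at 40.2 CPM in Kupffer day 0 a, 997 in b and 33.7 to 87.7 in CD40 day 2, and Jchain at 3.44, 141 and 1.82 to 8.34. Leaving out either Kupffer day 0 library left 1 of the 2 platelet genes called. Without Kupffer day 0 a, 1 neutrophil gene was higher and 4 lower, and 3 lipid-associated and lysosome genes were higher and 4 lower. With an estimated correlation 0 of the 26 lists were called after adjustment, and 3 had an unadjusted p under 0.05, while fry called 18. Leaving out 1 library brought some calls: hepatocyte genes without Kupffer day 0 a (camera adjusted p = 0.0013) or CD40 day 2 a (0.028), proliferation genes without Kupffer day 0 a (0.0069) or CD40 day 2 d (0.011), and neutrophil genes without Kupffer day 0 b (0.04).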

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

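Of the tests reported here, the one on the depth of library b was written before its result was seen, and the other tests of explanations were chosen after the values they use had been seen. The 4 CD40 day 2 libraries were searched for a library far from the other 3, over the 77 named genes and the shares of counts of 26 gene lists. Of 103 searches, 3 found one, where chance gives about 1 in 20, or 5.2. All 3 are in library a: Mrc1 at 23.7 CPM (12.7 to 13.7 in the others), Stab2 at 27.3 CPM (13.7 to 15), and Aldoa at 2700 CPM (2170 to 2260).

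The row n-R5s8 holds 2387 counts in Ly6C CD40-negative day 2 c and 0 in every Kupffer day 0 and CD40 day 2 library. The 2 columns a of the groups that are not read by gene have 1 step up from row to row, at this place. Sorting of the values apart from the gene names fits this number. A composition shared with Kupffer day 0, with each value under its own gene, is argued against, since the simulated libraries of that composition had at least 6707 steps up. No biological explanation was tested, and whether columns c and d of Ly6C CD40-negative day 2 keep part of the order of the names stays open. Their rank correlation with Kupffer day 0 a (0.9102 and 0.8896) argues against the whole order being kept, unless these cells resembled Kupffer day 0 that closely.

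A second pattern is the endothelial and stellate transcripts in the Kupffer day 0 libraries. Of the 27 measured genes of the 2 lists, 23 had 20 CPM or more there, and 9 in CD40 day 2. The most abundant, Clec4g, stood at 6840 CPM in Kupffer day 0 and 125 in CD40 day 2, and 27 of 27 genes were lower in every CD40 library than in both Kupffer libraries, although Mrc1 is also expressed by macrophages. RNA of endothelial and stellate cells in these libraries and expression of these genes by the Kupffer cells themselves cannot be told apart, because both would give this count, the median ratio of Kupffer library b to a differed by 0.18 ± 0.11 (SE, log2) between the endothelial and the Kupffer identity list, and there are 2 libraries. By list, the median log2 ratio of b to a was 0.03 ± 0.07 (SE) for endothelial, -0.15 ± 0.09 for Kupffer identity and -0.43 ± 0.21 for stellate genes. The endothelial and stellate medians lay on opposite sides of that of the Kupffer identity list. These standard errors are over genes of a single pair of libraries and measure no spread between libraries, so no pattern is read from this. How the cells were sorted is not given in the sources used here, and a difference between the labels or days stays open as a biological explanation, untested.

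In the third pattern, CD40 day 2 library b stands apart, with 453 of 5534 genes at least 2-fold from the median of the other 3 libraries, against 168, 77 and 193 genes for libraries a, c and d. A lower depth of library b is argued against as the whole cause, by library c alone: thinned to the depth of b, c had 137 such genes. Before thinning c had the fewest, 77. Libraries a and d were not thinned, so how many such genes they would have reached is not known. More RNA of mature dendritic cells in library b may contribute, since the conventional dendritic cell list took 0.146% of its counts, 1.7 times the highest of the other 3. Proliferation genes, at 0.123% against 0.0372% to 0.0634%, and plasmacytoid dendritic cell genes, at 0.0164% against 0.00349% to 0.00888%, stood out there as much. The share of the conventional dendritic cell list therefore does not single out mature dendritic cells. Co-stimulation and maturation genes, at 0.292% against 0.128% to 0.193%, were also highest there, by a smaller ratio. The classical monocyte list took 2.79% there against 3.68% to 4.05%, and a difference in state of the same cells was not tested.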

How the results depend on the processing

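Library size alone, the fit of all 12 libraries and, for the lists, other scalings and filters were chosen after seeing the data. Under the alternatives the count of genes changed between CD40 day 2 and Kupffer day 0 ranged from 3850 (10 counts in 4 libraries) to 6158 (no filter), against 5262, and leaving out each library gave 3206 (without Kupffer day 0 a) to 5514. No gene called in both fits changed direction under any alternative run. Of the calls, 59.3% were kept without Kupffer day 0 a and 92.8% without CD40 day 2 a. Library size alone shifted the median log2 fold change by -0.167, the minimum of 10 counts in 4 libraries by -0.129 and no other by over 0.1. Library size alone gave 35.9% of calls upward, against 43.5%. The fit of all 12 libraries gave 5039 genes, DESeq2 4568, RLE factors 5249 and a minimum log2 fold change of 1 4115. Gene lists called were 17, and 17 to 18 with a library left out, but 0 with an estimated correlation. Both the 4 residual degrees of freedom and the correlation within lists enter that test, and which of them removed the calls was not tested. At these library numbers a simulated list of 20 genes shifted 2-fold had a camera p of 0.00035 with an estimated correlation. The simulated genes were independent of each other, so this does not show what the test finds in correlated lists. The minimum of 10 counts gave 15 lists, since the dendritic cell list was lost and the stellate list had too few genes left to test, while no filter and the fit of all 12 libraries each gave 19. Of 911 values of the 77 named genes under alternatives, 907 kept their direction and side of the threshold and 4 lost the call: Itgax (2.47) and Htr7 (6.93) without Kupffer day 0 a, and mt-Nd4 (-1.57) and mt-Cytb (-1.18) in the fit of all 12 libraries. The cause of these losses was not tested. The fit of all 12 libraries takes part of its dispersion from 6 columns not shown to follow the gene names. Its counts of genes and lists, and the calls lost in it, therefore do not show how stable the calls are. For Htr7, with 0 counts in Kupffer day 0, 6.93 is a fitted value, and its fold is known only as a lower bound. No paired analysis was possible because the columns carry no replicate numbers. Alternatives for the 3 comparisons that are not analysed here were not run, nor were replicate blocks. At the library numbers, depths and dispersion of this comparison, a change of 2-fold was called in 48 of 100 simulated genes and a change of 4-fold in 100 of 100. No other library numbers, depths or dispersion were simulated.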

Other observations

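Genes that the rule did not name, chosen here after their values were seen, add to the account of CD40 day 2 against Kupffer day 0. Single genes that rose were Saa3, a serum amyloid, at 6010 ± 2550 CPM (SD, n = 4) against 132 (edgeR log2 fold change 5.5, adjusted p = 2.51e-05), Hp, haptoglobin, at 1590 ± 638 against 199 (3.02, adjusted p = 0.000452), and Lcn2, lipocalin-2, at 61.4 against 18.2 CPM (1.8, adjusted p = 0.000244). Among the hepatocyte list, the 3 members that rose were Ass1, Saa1 and Saa2, of which Ass1 makes arginine precursors and is also used by activated macrophages, while Alb fell from 148 to 18 CPM and Apoc1 from 730 to 35.5, and Hpx (adjusted p = 0.125) and Fgg (0.967) did not pass the test. Prdx5 was at 5480 ± 1390 against 538 CPM, Txn1 at 11800 ± 2790 against 2830 and Sod2 at 2140 ± 698 against 197.

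Members of the lysosome and lipid list, which was not called, went both ways. Apoe fell from 12000 to 714 ± 408 CPM (log2 fold change -4.07, adjusted p = 2.35e-05) and the protease Ctsl from 2520 to 209 ± 125 (-3.57), while Lgals3, galectin-3, rose from 506 to 4140 ± 930 (3.03) and Ctsz from 376 to 2820 ± 263 (2.91). Of the complement genes, C3 rose from 44.7 to 395 CPM, whereas C1qb was at 1320 CPM in both groups (adjusted p = 0.997). C1qa was at 226 against 460 CPM (-1.01, adjusted p = 0.0348). In the cytokine list, Cxcl13 fell from 62.5 to 1.02 CPM (-5.98) and Csf1 from 105 to 11.8 (-3.15), and Il1b was at 908 against 462 (0.98, adjusted p = 0.00288).

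The 2 Kupffer day 0 libraries differed in transcripts of other cells. The B cell and plasma cell list took 0.00738% of counts in a and 0.123% in b, the neutrophil list 0.105% and 0.345%, and the hepatocyte list 0.142% and 0.284%. With 2 libraries no test of this was made.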
